A study of Cicer arietinum with 12 samples.

How the data were processed

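Gene expression was measured by RNA sequencing of leaf RNA from 12 samples of chickpea, 3 in each of 4 groups made by the genotypes ICC283 and ICC8261 and the well-watered and drought-stressed treatments. Per the labels' protocols, plants grew in a glasshouse at 23 to 28 degrees Celsius, 6 pots per genotype were allotted at random to the treatments, and HiSeq 1000 sequencing gave paired reads of 150 bases. The labels do not say in so many words that each library is a separate pot, so p-values measure the spread between these libraries. Samples were grouped by the labels' titles and treatment entries.

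The authors deposited 1 file of whole-number counts per gene and library. Per the submitters' processing notes the tools were Trimmomatic, TopHat2 2.1.1, Cufflinks 2.0.2, HTSeq, DESeq2 and edgeR. The genome build, the annotation and the strand setting are not given in the sources used here. Each count file ends in 5 HTSeq summary lines, which were kept out of library sizes and tests. Between 44.1% and 53.5% of all counted lines in a library were alignments that were not unique, between 16.6% and 21.4% fell on no feature, and between 0.179% and 0.388% were ambiguous. In the 8 libraries with the same treatment in both sources the share not unique was higher under drought, 53.4% and 53.5% against 50.6% and 48.1% in ICC283 and 52.8% and 50.5% against 46.7% and 44.1% in ICC8261. In the 4 libraries of conflicting treatment it was 50.5%, 48.5%, 49.3% and 50%. The share on no feature was lower, 16.6% and 16.9% against 19.3% and 20.1%, and 18.2% and 16.9% against 20% and 21%. Which genes lost reads this way was not measured. The gene with most counts, LOC101500093, took between 6.34% and 18.4% of the counts of a library.

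The authors also deposited tables of their comparisons per genotype. Per the file headers these hold log2 fold changes, p-values and adjusted p-values from DESeq2 for all genes and from edgeR for the genes listed, and the DESeq2 tables add a column of normalized counts per library, entered here as a signal. In each of these 12 deposited columns the values were whole multiples of the smallest value above 0, within a tolerance of 0.02 for 100% of values, so whole reads were recovered. The recovered reads were compared with each count file at 27233 genes. Every column equalled exactly 1 count file, and no other pair was equal at more than 24.1% of the genes. For 4 libraries the treatment in the table column differs from that of the matching count file. Which of the sources is right was not given in the sources used here.

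The planned fit used the count files with their labels. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, 1 model with 4 group means, glmQLFit with robust estimation and a two-sided glmQLFTest, with Benjamini-Hochberg adjustment over all genes tested and calls at 0.05. The spread was shared over the 4 groups. The contrasts were drought in each genotype, their difference, their mean, and the genotype difference under each treatment, 6 in all. These choices and their alternatives were fixed before the data were examined. Further versions of the fit were added after the conflict had been seen, and their counts were known when the text was planned: all 12 libraries with the tables' labels and recovered reads, and only the 8 libraries with the same treatment in both sources. The latter leads the gene descriptions because it needs no decision between the sources. The SE of a log2 fold change is its absolute value over the square root of the quasi-likelihood F.

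The reference table of gene names (assembly Cicar.CDCFrontier_v2.0) matched 24445 of the 27234 features, 89.8%. It gives symbols but no product names. The 45 gene lists fixed beforehand relied on product names and could not be used. In their place 19 lists were set from gene symbols after the gene names had been seen and before any test. Of these, 18 had at least 5 members in the files, and 17 were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with adjustment over lists, after the filter left 5 members or more. Camera with an estimated correlation and fry were alternatives. Camera compares list members with other genes, while fry asks only whether the members moved in a shared direction. List members are called on adjustment over all genes.

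Named genes have a symbol and were taken by a rule fixed beforehand, applied to the 8-library fit: adjusted p under 0.05, a mean of at least 2 CPM in the higher group, and complete separation of the libraries except for the difference; of these the 8 largest rises and falls per drought contrast and 6 for the others; up to 3 members per list and direction with the smallest p; and every measured member of the dehydrin, LEA and osmolyte list. List members needed no minimum level or separation. The rule fixed beforehand required a product name and, with product names missing for all genes, allowed at most 2 IDs per direction; here a symbol stood in for the product name, a departure from that rule, and the hormone synthesis list it also named could not be matched. A call in the same direction with the tables' labels was added as a condition. A gene's values in a contrast other than the one that named it, the genes drawn as single panels, and GRP1 in the single genotypes were chosen after their values were seen.

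On simulated counts with 200 changed genes, the test of drought in ICC283 recovered 94% of 4-fold and 50% of 2-fold changes in 12 libraries (18256 genes), and 85% and 34% in 8 libraries (18299 genes). Of the calls, 5.26% and 3.25% were false. The simulation gave unchanged genes the same mean in all groups, a trended spread and no outlying library. These shares therefore may not carry over to the measured libraries. The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a stricter filter of 10 counts in every library of a group, no robust estimation, leaving out the 20 most abundant genes, the replicate number as a block, fits of 1 genotype or treatment alone, a fold threshold, and leaving out each library.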

Results

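Leaf RNA of chickpea (Cicer arietinum) was sequenced from plants at the shoot apical meristem stage. The genotype ICC8261 is called drought tolerant in the labels and ICC283 drought sensitive, and each was grown well-watered at 80% of field capacity or drought-stressed at 20%. The 4 groups held 3 libraries each, 12 in all. The count files assigned between 8910704 and 12192098 reads per library to genes, and between 20477 and 22105 genes had at least 1 read. The stated aim was to find genes that respond to drought and how transcription factor and hormone genes differ between the genotypes.

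The treatment of 4 libraries differed between the deposited sources. The normalized columns of the authors' deposited tables, turned back into whole reads, equalled the count files at all 27233 shared genes, but not always under the same treatment. The reads filed as ICC283 well-watered library 3 stood in the tables as ICC283 drought library 3, and the reverse. The reads filed as ICC8261 well-watered library 1 stood there as ICC8261 drought library 2, and the reverse. Genotype was the same in both sources for all 12 libraries, and 8 libraries, 2 per group, had the same treatment in both. With the count-file labels, edgeR's quasi-likelihood test called 0 genes under drought in either genotype at an adjusted p of 0.05, while 1841 genes in ICC283 and 386 in ICC8261 had an unadjusted p under 0.05, and DESeq2 called 46 and 0. The quasi-likelihood test called 6831 genes in ICC283 and 3468 in ICC8261 with the tables' labels, and 7167 and 2898 in the 8 agreed libraries. Gene values below come from the 8 agreed libraries (n = 2 per group, edgeR log2 fold change ± SE), and a gene is described as having risen or fallen only where the 12-library fit with the tables' labels called it in the same direction. That rule was chosen after the conflict and the counts had been seen. The 8 libraries are part of those 12, with the same reads and labels. A call in both fits is therefore not independent support.

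**Figure D1:**
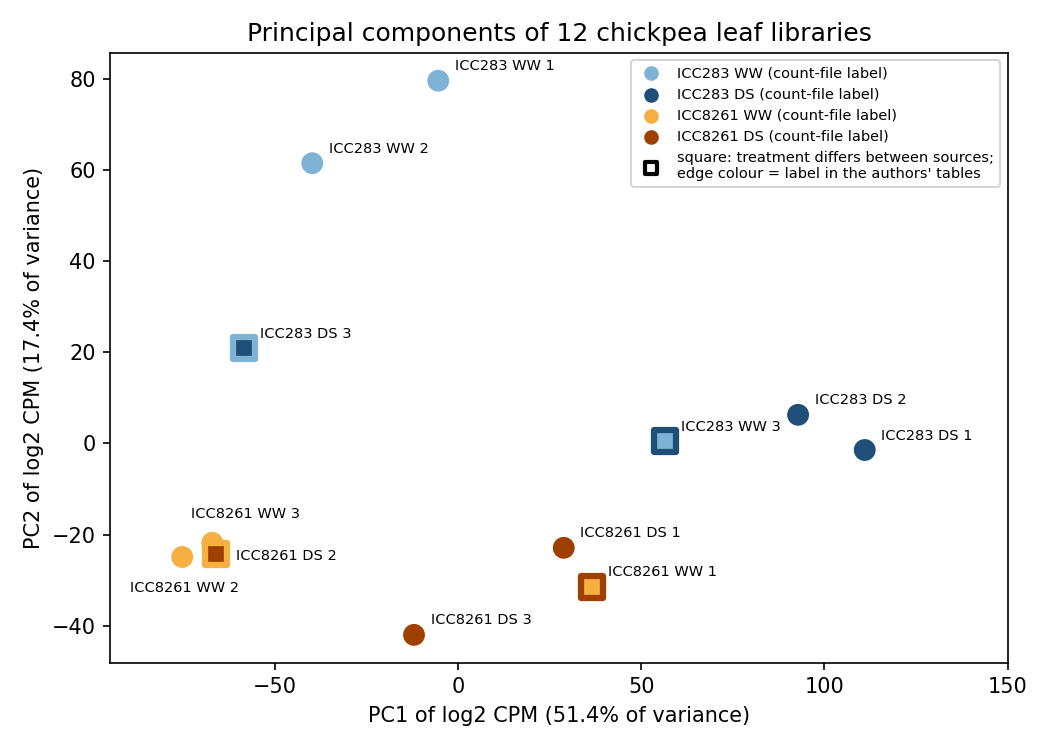
Principal components of log2 CPM of the 12 libraries, with PC1 (51.4% of the variance) on the horizontal and PC2 (17.4%) on the vertical axis; fill colour is the count-file group. Squares mark the 4 libraries whose treatment differs between the sources and carry the tables' group as edge colour. The library filed as ICC8261 drought 2 has a PC1 score of -66.3, beside the well-watered libraries 2 and 3 at -75.4 and -67.2.

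Of 18541 genes tested in both fits, 2406 rose and 3196 fell in ICC283 under drought, the background for the list counts of this genotype. In ICC283 4 of 5 members of the dehydrin, LEA and osmolyte list rose. DHN, a dehydrin, rose from 7.78 ± 2.02 to 738 ± 9.61 CPM (SD, n = 2 each), a log2 fold change of 6.56 ± 0.51 (adjusted p = 2.6e-04). The ICC283 libraries of conflicting treatment, left out here, lay between these means, at 340 CPM (filed as well-watered) and 39.9 CPM (filed as drought). The median log2 fold change of the list was 5.22 in the 8 libraries and 4.19 with the tables' labels. CAPLEA-1 and CapLEA-2, named as late embryogenesis abundant proteins, rose by 7.40 ± 0.68 and 5.22 ± 0.52. CAPLEA-1 had 1 and 3 counts in the well-watered libraries, so the size of its rise is imprecise. P5CS, the proline synthesis enzyme, rose by 2.30 ± 0.57 (adjusted p = 0.021). The remaining tested member, CAGOLS1, a galactinol synthase symbol, had a value of -0.67 ± 0.27 (adjusted p = 0.077). Camera gave that list an adjusted p of 1.2e-05 with its preset correlation and an adjusted p of 0.58 with an estimated correlation. The preset test gave 0.41 with the count-file labels, the planned fit.

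Transcription factors of ICC283 moved in both directions. Of 51 tested NAC factors, a plant family of transcription factors, 4 rose and 15 fell in both fits. NAC4 rose by 2.84 ± 0.62, NAC52 by 2.37 ± 0.53 and NAC05 by 2.11 ± 0.25. NAC6 fell to 14.5 ± 0.116 CPM from 65.7 ± 1.81 (log2 fold change -2.18 ± 0.17, adjusted p = 4.9e-05), and NAC69, NAC43 and NAC39 had log2 fold changes of -2.06, -1.53 and -3.72. The NAC list had a camera adjusted p of 0.03, which was 0.58 with an estimated correlation, and 0.12 and 2.9e-04 with the tables' and the count-file labels. The homeodomain-leucine zipper gene CAHDZ12 rose by 3.75 ± 0.87 and BZIP by 0.70 ± 0.15, while CARERF1 (-1.75 ± 0.37) and CaWRKY50 (-2.0 ± 0.31) fell. Of 20 heat stress factors 1, HSFC1 (1.32 ± 0.32), rose in both fits, and 0 fell in both. Of 20 auxin response factors, 3 rose (ARF1, ARF3 and ARF20, between 0.54 and 0.75) and 3 fell (ARF13, ARF4 and ARF12, -0.97, -1.24 and -1.28). These shares are near those over all genes.

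Of 11 circadian clock genes, 6 rose and 1 fell in ICC283, and of 5 flowering regulators 1 rose and 1 fell. Neither list passed camera (adjusted p = 0.1 and 0.27, and 0.58 for both with an estimated correlation). The alternative test fry gave adjusted p of 0.036 and 0.041, and 0.87 and 0.91 with the count-file labels. Fry does not compare list members with other genes. In the 8 libraries 38.2% of all tested genes were called in ICC283 and fry passed 10 of 17 lists. A small fry value therefore does not set a list apart. The evening-phased TOC1A rose by 1.45 ± 0.15, PRR37B by 1.33 ± 0.13 and PRR59A by 1.06 ± 0.16, and the morning-phased LHY fell from 186 ± 2.29 to 57.1 ± 0.455 CPM (-1.70 ± 0.20, adjusted p = 3.1e-04). FTA1, a member of the FLOWERING LOCUS T family, rose from 3.97 ± 0.3 to 69.7 ± 0.967 CPM (4.13 ± 0.31, adjusted p = 5.2e-05). FT-B, of the same family, had a log2 fold change of -3.95 ± 0.87 from a mean of 1.62 CPM. The labels do not give the time of day of harvest, so a difference in harvest time between groups is not ruled out for the clock genes in any contrast.

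Some genes of secondary metabolism and of the cell wall were among those that fell in ICC283. Of 50 UDP-glycosyltransferases, enzymes that attach sugars to small molecules, 16 fell and 1, UGT85X1 (1.19 ± 0.17), rose. UGT85K8 had a log2 fold change of -4.59 ± 0.54, UGT88E8 of -2.34 ± 0.30 and UGT73C15 of -1.66 ± 0.15. Camera gave this list an adjusted p of 0.023, an adjusted p of 0.58 with an estimated correlation, and 0.035 with the count-file labels. The share of alignments that were not unique was higher under drought in the 8 libraries (53.4% and 53.5% against 50.6% and 48.1% in ICC283), and its effect on single families was not measured. Of 10 phenylpropanoid and isoflavonoid enzymes 4 fell and none rose, among them PAL (-1.52 ± 0.26), the entry enzyme of the pathway, and CYP73 (-1.08 ± 0.23). Of 7 cell wall genes 4 fell and none rose: the expansins EXPA1 (-3.13 ± 0.60) and CA-EXPA2 (-1.74 ± 0.41), XTH1 (-4.10 ± 1.14, adjusted p = 0.04) and pme1 (-0.99 ± 0.19). Neither list passed camera (adjusted p = 0.1 and 0.36). The alternative test fry gave adjusted p of 0.057 and 0.048, and 0.68 and 0.91 with the count-file labels. Again fry makes no comparison with other genes. In the count-file fit EXPA1, CA-EXPA2 and XTH1 turned to 0.40, 0.55 and 0.49, and 6 of the 7 cell wall genes were above 0 (median 0.49, adjusted p = 0.85). In the 8 libraries TUBB, a tubulin, and ACTIN, in common use as reference genes, fell (-0.98 ± 0.15 and -2.97 ± 0.55). ACTIN was at 0.10 in the count-file fit. Among the largest changes of other symbols were GRP2 (4.86 ± 0.49) and LTP (2.72 ± 0.23), which rose, and lrr (-6.02 ± 0.44), UGT72AB1 (-4.36 ± 0.89) and CAAP1 (-4.12 ± 0.97), which fell; lrr was at 0.02 in the count-file fit.

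Of 14 MAP kinases in ICC283 2 fell in both fits, MAPK11 (-0.92 ± 0.13) and MAPK9 (-1.32 ± 0.46), while the fit with the tables' labels alone called 3 higher and 2 lower. In addition 2 of 5 CAMKK genes fell, CAMKK2 (-0.91 ± 0.15) and CAMKK6 (-1.58 ± 0.54). Of 5 calcium signalling genes CDPK2, calmodulin and CAM fell (-0.82, -0.65 and -0.47). None of these 3 lists passed camera (adjusted p = 0.55, 0.29 and 0.39). The alternative test fry gave adjusted p of 0.0026, 0.001 and 0.0034, and 0.11, 0.32 and 0.87 with the count-file labels. Fry makes no comparison with other genes, so these values do not set the lists apart from the response of all genes. ACS, a symbol of the ethylene synthesis enzyme, fell by 1.30 on the log2 scale (SE 0.16). FER1, a ferritin, rose by 1.16 ± 0.28. The calls in ICC283 were 3210 higher and 3957 lower of 18750 genes tested, 3892 of them with an absolute log2 fold change of at least 1. They were 3087 and 3744 of 18591 with the tables' labels, and 5602 genes were called in the same direction in both fits. Without ICC283 drought library 1 the 8-library count was 3961.

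**Figure D2:**
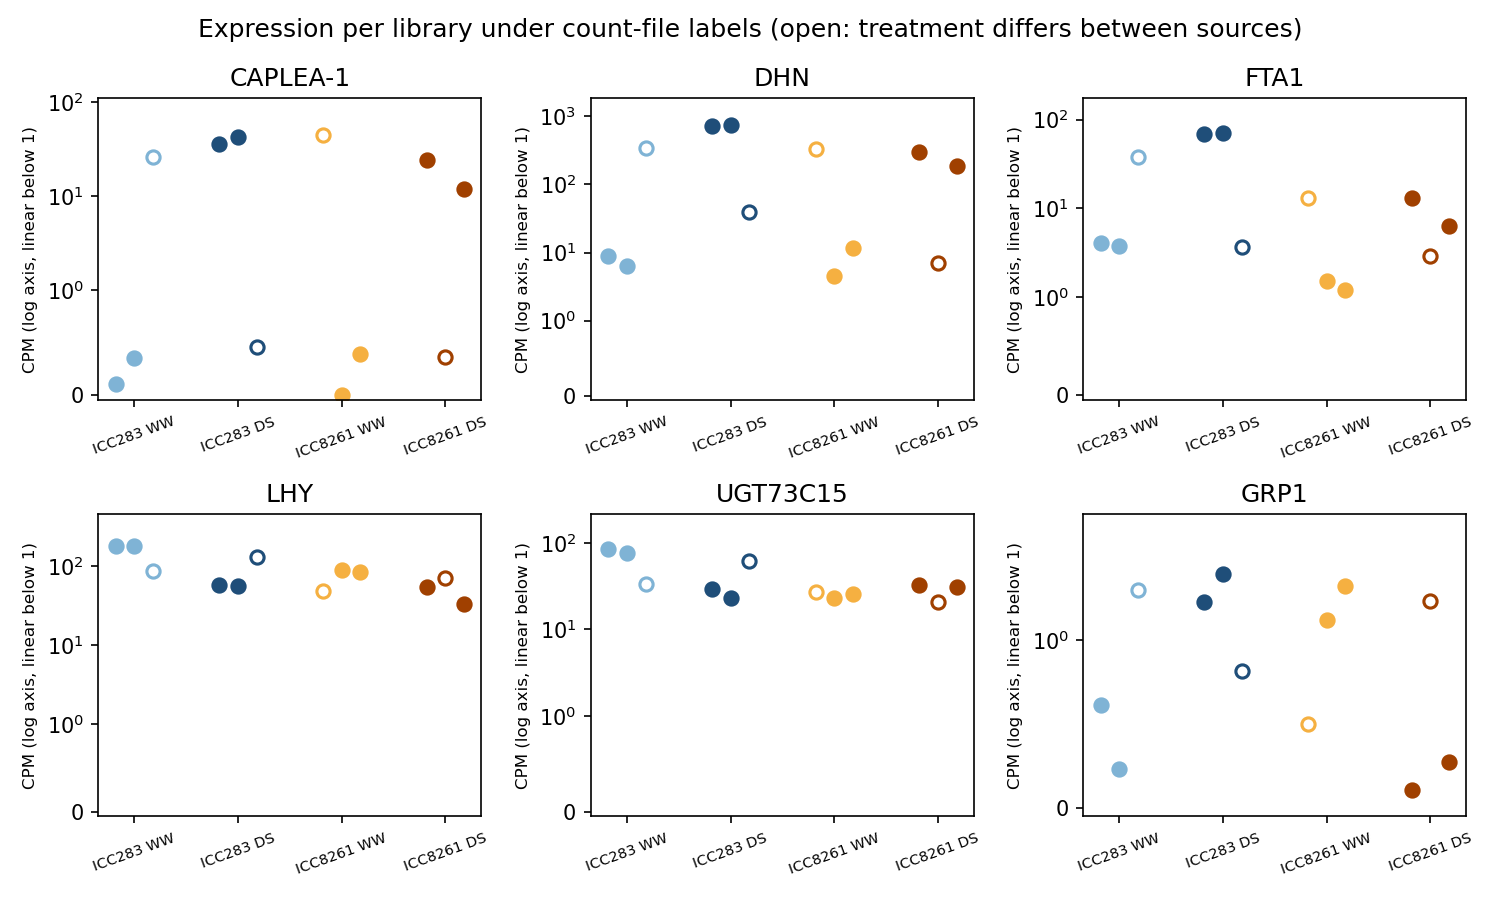
Expression of 6 genes in CPM (log axis, linear below 1), 1 point per library under the count-file labels, with the libraries of conflicting treatment as open circles. In the library filed as ICC283 well-watered 3, DHN is at 340 CPM, against 9.02 and 6.26 in well-watered libraries 1 and 2.

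Of 18541 genes tested in both fits, 1341 rose and 952 fell in ICC8261 under drought, the background for its list counts. In ICC8261 3 of the 5 dehydrin, LEA and osmolyte genes rose. DHN rose from 8.07 ± 5.13 to 243 ± 76.7 CPM (SD, n = 2 each; log2 fold change 4.92 ± 0.47, adjusted p = 0.0022), CAPLEA-1 by 6.45 ± 0.67 and CapLEA-2 by 3.85 ± 0.44. CAPLEA-1 had 0 and 5 counts in the well-watered libraries, so the size of its rise is imprecise here too. P5CS had a value of 0.94 ± 0.51 (adjusted p = 0.26) and CAGOLS1 of -0.11 ± 0.27 (adjusted p = 0.81). In the count-file fit CAPLEA-1, P5CS and CAGOLS1 turned to -0.29, -0.43 and 0.02. Camera gave the list of 5 an adjusted p of 1.7e-07, an adjusted p of 0.29 with an estimated correlation, and 0.78 with the count-file labels. CAHDZ12 rose by 3.74 ± 0.86, FTA1 by 2.84 ± 0.36, HP3 by 2.41 ± 0.37 and F-BOX1 by 2.1 ± 0.30.

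Of 51 NAC factors 3 rose in ICC8261, NAC05 (2.04 ± 0.28), NAC11 (1.86 ± 0.36) and NAC5 (1.47 ± 0.25), and NAC66 fell (-2.24 ± 0.61). HSFC1 rose by 2.03 ± 0.33. TOC1A, PRR59A and PRR37B rose by 0.94, 0.81 and 0.60, and LHY fell from 87.5 ± 4.1 to 43.6 ± 15 CPM (-1.01 ± 0.20, adjusted p = 0.011). In the count-file fit TOC1A turned to -0.13, PRR59A, PRR37B and LHY were at 0.10, 0.01 and -0.50 (adjusted p = 1), and 8 of the 11 clock genes lay below 0 (median -0.12). Of 20 auxin response factors 4 fell and none rose: ARF12 (-1.40), ARF6 (-1.22), ARF13 (-0.98) and ARF4 (-0.83). Of 50 UDP-glycosyltransferases 3 rose, led by UGT85X1 (1.85 ± 0.17), and 2 fell, UGT85K8 (-2.38 ± 0.42) and UGT85H3 (-0.75 ± 0.20, but 0.25 in the count-file fit). EXPA1 fell (-2.26 ± 0.49), as did lrr (-1.60 ± 0.27) and Bglc-2 (-1.33 ± 0.30). MAPK7 rose by 0.66 ± 0.14.

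The metallothioneins MT-1 and MT-2, small metal-binding proteins, rose in ICC8261 by 1.42 ± 0.17 and 0.87 ± 0.19. Their list of 5 with ferritins had a camera adjusted p of 0.0024, an adjusted p of 0.53 with an estimated correlation, and 0.12 and 8.5e-06 with the tables' and the count-file labels. Of 14 reference and ribosomal protein genes 4 fell and none rose, including IF4A (-0.64 ± 0.14), EF1A (-0.79 ± 0.21) and actin (-0.42 ± 0.11). That list's adjusted p was 0.0089, 0.71 with an estimated correlation, and 0.9 with the count-file labels. The calls were 1704 higher and 1194 lower of 18750, 1250 of them with an absolute log2 fold change of at least 1. With the tables' labels they were 1828 and 1640, and 2293 genes were called in the same direction in both fits. That fit's count of 3468 was 2283, 1510 and 2165 without ICC8261 well-watered libraries 1, 2 and 3, and 1713 and 1630 without drought libraries 1 and 2, as numbered in the tables. The 8-library count was 455 without ICC8261 well-watered library 2, 1242 without well-watered library 3 and 1101 without drought library 1, and 1800 with the replicate number as a block.

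**Figure D3:**
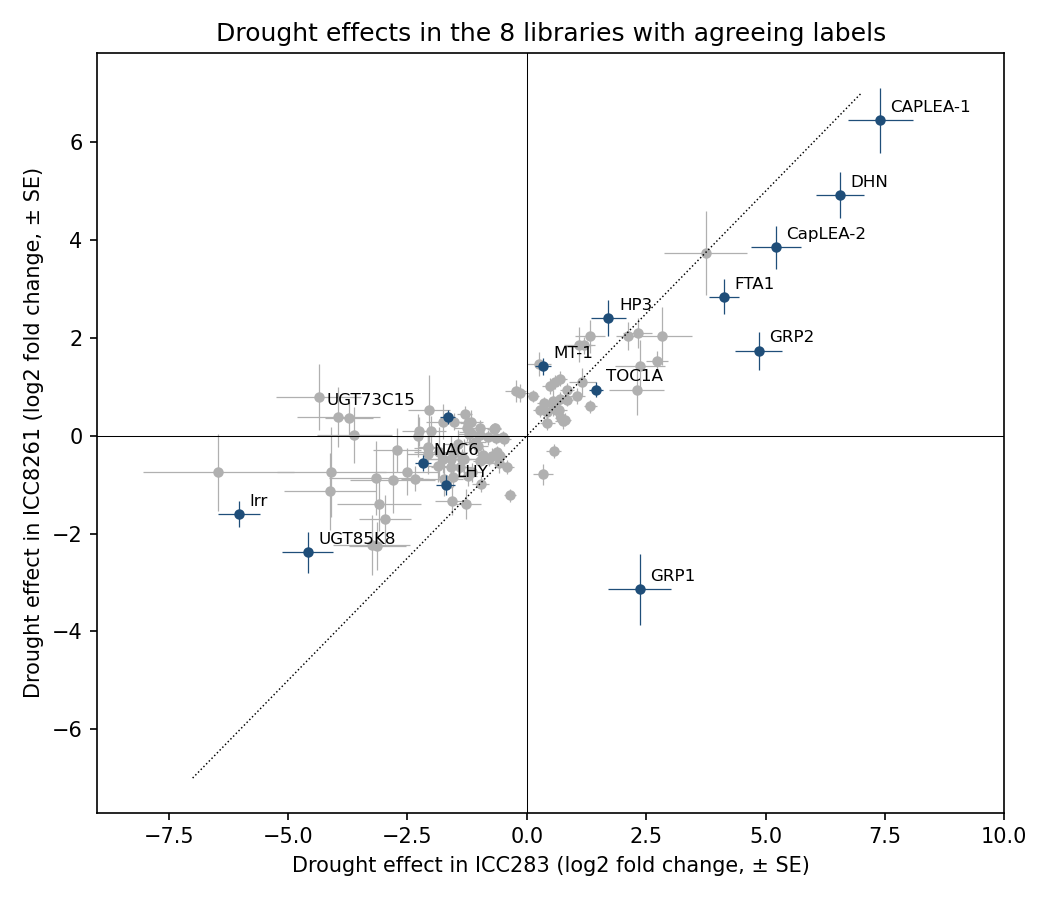
Drought effects (log2 fold change ± SE, 8 agreed libraries) in ICC283 on the horizontal axis and ICC8261 on the vertical axis, for 118 genes with a symbol called in at least 1 genotype in both fits. The dotted line marks equal effects. DHN lies at 6.56 and 4.92, and GRP1 is at 2.36 and -3.14.

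Genes called under drought were shared between the genotypes more often than independent lists would be. In the 8 agreed libraries 901 genes were called higher in both genotypes, against 292 for independent lists (Fisher's exact test, odds ratio 7.16, p = 4.4e-282), and 818 were called lower in both, against 252 (odds ratio 9.99, p = 2.4e-295). Genes are not independent replicates, so these p-values describe the lists. With the tables' labels 1082 and 1202 genes were shared in each direction. The log2 fold changes correlated across genes with a Spearman rho of 0.5 (0.62 with the tables' labels). With the count-file labels, the planned fit, rho was 0.2 and 0 genes were called in both genotypes. In the 8 libraries 122 of the 1841 genes called in both genotypes had opposite signs.

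The difference between the drought effects was tested directly as ICC8261 minus ICC283. Of 51 NAC factors 4, and of 50 UDP-glycosyltransferases 2, passed this test in both fits, all with a positive difference. Over all 18541 genes tested in both fits, 284 passed with a positive and 173 with a negative difference. NAC6 had a difference of 1.62 ± 0.24 (adjusted p = 0.0049), NAC69 of 1.82 ± 0.32, NAC47 of 1.82 ± 0.41 and NAC51 of 2.36 ± 0.46. UGT73C15 fell to 26.3 ± 4.61 from 83.3 ± 6.93 CPM in ICC283 and was at 24.3 ± 1.58 and 31.6 ± 0.705 CPM in ICC8261, a difference of 2.04 ± 0.21 (adjusted p = 0.0015). UGT71S1 differed by 1.25 ± 0.32 and ACS by 1.75 ± 0.22. GRP1 differed in the opposite sense by -5.49 ± 0.97 (adjusted p = 0.0095): it had log2 fold changes of 2.36 ± 0.65 in ICC283 and -3.14 ± 0.73 in ICC8261, on means of at most 2.29 CPM. None of the 5 dehydrin, LEA and osmolyte genes passed this test, and DHN had a difference of -1.64 ± 0.62 (adjusted p = 0.14) that was 0.10 with the tables' labels.

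As lists, NAC factors had a positive difference (43 of 51 members above 0, camera adjusted p = 6.6e-04) and so did UDP-glycosyltransferases (46 of 50, adjusted p = 5.0e-04). With an estimated correlation both adjusted p were 0.36. With the tables' labels the preset test gave 5.8e-04 and 7.7e-06, and with the count-file labels 0.0023 and 0.0024. In the 8 libraries the well-watered ICC283 group is libraries 1 and 2, which stood apart from the others on PC2 (79.6 and 61.5, next highest 20.9). In that fit the well-watered level of ICC283 rests on that pair. The pair also makes up 2 of the 3 well-watered ICC283 libraries under the tables' and the count-file labels. The list values of those versions therefore rest partly on the same pair. The drought effect in ICC283 uses the same well-watered group, so the values of both lists there are not separate support. The 8 agreed libraries gave 2355 calls, 1478 positive and 877 negative, and the tables' labels 479, of which 457 were called in both in the same direction. The count-file labels gave 0 by edgeR, with 634 at an unadjusted p under 0.05, and 0 by DESeq2. The median of all genes was 0.12 in the 8 libraries and 0.05 with upper-quartile scaling. The 8-library count was 540 without ICC283 drought library 1, 1049 without drought library 2, 694 and 1156 without ICC8261 well-watered libraries 2 and 3, and 1561 without ICC8261 drought library 1; with the tables' labels it was 277, 57 and 2298 without ICC283 well-watered libraries 1 to 3, 55, 112 and 918 without drought libraries 1 to 3, 223, 65 and 85 without those of ICC8261 well-watered, and 79, 192 and 274 without those of ICC8261 drought.

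Averaged over both genotypes, drought raised CAPLEA-1 (6.92 ± 0.48), DHN (5.74 ± 0.35), CAHDZ12 (3.75 ± 0.61), FTA1 (3.48 ± 0.23), F-BOX1 (2.21 ± 0.22), NAC05 (2.07 ± 0.19) and HSFC1 (1.67 ± 0.23). UGT85K8 (-3.49 ± 0.34), lrr (-3.81 ± 0.26), HSFB4 (-3.0 ± 0.57), EXPA1 (-2.69 ± 0.39), LHY (-1.35 ± 0.14) and PRR59C (-0.67 ± 0.12) fell. CAPLEA-1 had few counts in the well-watered libraries of both genotypes, so the size of its rise is imprecise. The dehydrin, LEA and osmolyte list had a camera adjusted p of 4.2e-08, an adjusted p of 0.27 with an estimated correlation, and 0.38 with the count-file labels. The calls were 3635 higher and 3932 lower in the 8 libraries, and 3863 and 4314 with the tables' labels. With the count-file labels the quasi-likelihood test called 0, with 1405 genes at an unadjusted p under 0.05, and DESeq2 called 22.

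Under well-watered conditions 2 of 5 flowering regulators were higher in ICC8261, a list with a camera adjusted p of 0.2 in the 8 libraries and 0.041 with the tables' labels (0.5 and 0.28 with an estimated correlation). It was 0.0034 with the count-file labels, and 0.21 with an estimated correlation. FTA2, of the FLOWERING LOCUS T family, was higher in ICC8261 by 7.65 ± 0.59 (adjusted p = 4.1e-04), and ARF23 by 3.26 ± 0.27. FD, the bZIP partner of FLOWERING LOCUS T, was higher by 0.88 ± 0.19 and Bglc-2 by 2.85 ± 0.32. Both genotypes were counted on the same gene features. Whether a difference such as that of FTA2 lies in expression or in the mapping of reads was not tested. In the 8 libraries LOC101494948 had no counts in ICC283 (10.14), and LOC101497567 had none in ICC8261 (-8.83). Over all 18541 genes tested in both fits, 807 were higher and 1324 lower in ICC8261. Of 51 NAC factors 9 were lower in ICC8261 and none higher, among them NAC05 (-1.84 ± 0.28), NAC5 (-1.77 ± 0.26) and NAC43 (-1.75 ± 0.18). NAC43 was at 42.6 ± 0.414 CPM in ICC283 libraries 1 and 2, the pair apart on PC2, and at 33.4 ± 14.7 with the third well-watered library of the tables. Of 20 heat stress factors 3 were lower, HSFA4C (-2.62 ± 0.48), HSFA6B (-2.18 ± 0.33) and HSFB1A (-1.84 ± 0.28). Of 50 UDP-glycosyltransferases 13 were lower and 1 higher, with UGT71S1 at -2.19 ± 0.23. Of 10 phenylpropanoid and isoflavonoid enzymes 2 were lower (camera adjusted p = 0.17), and cyp81E3v2 was lower by -4.74 ± 0.55. MT-1 and MT-2 were lower (-1.26 ± 0.17 and -1.20 ± 0.19), as was LHY (-1.08 ± 0.19).

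Camera gave adjusted p = 0.0056 for the NAC list, 0.013 for the heat stress factors, 0.0056 for the UDP-glycosyltransferases and 0.0056 for 8 other transcription factors. With an estimated correlation these adjusted p were 0.32, 0.27, 0.32 and 0.27, and with the tables' labels the preset test gave 0.0058, 0.017, 4.1e-04 and 0.074. It gave 0.034, 0.0023, 0.0034 and 0.32 with the count-file labels. The well-watered ICC283 group enters this contrast, drought in ICC283 and the difference. The NAC and UDP-glycosyltransferase values of these contrasts are therefore not independent support. In the genotype difference under drought, which that group does not enter, camera gave them adjusted p of 0.64 and 0.46 in the 8 libraries. Well-watered, the calls were 2114 higher and 2878 lower in ICC8261, 42.3% higher, which upper-quartile scaling turned to 2863 and 2262 (55.9%). With the tables' labels there were 952 and 1404, and with the count-file labels 45 and 53. The 8-library count was 1967 without ICC283 well-watered library 1, and 1434 and 2418 without ICC8261 well-watered libraries 2 and 3. The tables' count was 906, 1073 and 5449 without ICC283 well-watered libraries 1, 2 and 3, and 1398, 697 and 1014 without those of ICC8261. FTA2 and ARF23 had log2 differences of 8.22 and 3.61 under the count-file labels.

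Under drought FTA2 and ARF23 were again higher in ICC8261, by 7.63 ± 0.52 and 3.88 ± 0.27. A difference in the mapping of reads was not tested here either. lrr (4.99 ± 0.47), the protease inhibitor symbol kpi1 (3.92 ± 0.25), NAC39 (3.90 ± 0.49), NAC50 (2.71 ± 0.40) and CHS, chalcone synthase of flavonoid synthesis (2.04 ± 0.36), were higher too. FTA1 was lower in ICC8261 (-2.85 ± 0.27, adjusted p = 5.1e-04), as were NAC05 (-1.90 ± 0.25), UGT72X1 (-1.94 ± 0.50) and HSFA6A (-1.49 ± 0.30). Of 51 NAC factors 5 were higher and 2 lower, and of 50 UDP-glycosyltransferases 5 and 2. Over all 18541 genes tested in both fits, 1006 were higher and 676 lower. The calls were 2043 higher and 1508 lower in the 8 libraries, 1150 and 763 with the tables' labels, and 69 and 44 with the count-file labels. Camera gave adjusted p = 0.013 for the circadian clock, 0.029 for the heat stress factors, 0.029 for the cell wall genes and 0.028 for the defence proteins, and with an estimated correlation these adjusted p were 0.73, 0.3, 0.3 and 0.3. With the tables' labels the preset test gave 0.16, 0.057, 0.12 and 0.19, so none of these 4 lists passed there. It gave 0.39, 0.044, 0.39 and 0.39 with the count-file labels. The flowering regulators had 0.46 in the 8 libraries, 0.19 with the tables' labels and 2.3e-05 with the count-file labels, where the estimated correlation left 0.025 with 1 of 5 members called. The 8-library count was 862 and 1602 without ICC283 drought libraries 1 and 2, and 1773 without ICC8261 drought library 3. The tables' count was 3034 without ICC283 well-watered library 3, 673 and 628 without ICC283 drought libraries 1 and 2, and 979 and 779 without ICC8261 drought libraries 1 and 3.

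The authors' deposited tables were compared with these fits. The authors' deposited DESeq2 table listed 5198 genes of ICC283 at an adjusted p under 0.05, 2054 higher and 3144 lower, and that of ICC8261 listed 4738, 2248 higher and 2490 lower. Of those tested here with the tables' labels, 97.9% in ICC283 and 69.6% in ICC8261 were also called in the same direction. In the 8 agreed libraries these shares were 90.1% and 54.3%. With the count-file labels the sign was the same for 89% and 85.8% of the genes that the authors' deposited DESeq2 tables list under 0.05 and that were tested here. That fit called 0 of these genes in either genotype. The authors' values come from the same reads, and 8 libraries carry the same treatment in both sources. These shares are therefore not independent support.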

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

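The tests of the labels, of single libraries and of other sample splits were chosen after the results had been seen; the test of replicate closeness was planned before its result.

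The drought effect differed between the genotypes, by a test of the difference itself, for 457 genes called with the tables' labels and in the 8 agreed libraries, versions taken up after the data had been seen. In the planned fit with the count-file labels edgeR called 0, with 634 genes at an unadjusted p under 0.05, and DESeq2 called 0. The tables' count of 479 ranged from 55 to 2298 when 1 library was left out, with 55 without ICC283 drought library 1. Among genes with a symbol the difference in the 8 libraries (ICC8261 minus ICC283, log2) was 2.36 for NAC51, 2.04 for UGT73C15, 1.82 for NAC69, 1.82 for NAC47, 1.75 for ACS, 1.62 for NAC6, 1.51 for atpF, 1.25 for UGT71S1 and -5.49 for GRP1.

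The treatment of 4 libraries differed between the count files and the authors' deposited tables. An exchange of labels in the count files is a candidate explanation: at the genes called under drought in the 8 agreed libraries, the 4 lay nearer the group named in the tables at 76.5%, 71.9%, 92.9% and 86.9% of the genes, and a wrong label in the tables would need 50% or less. All 4 shares, from the lowest of 71.9% to the highest of 92.9%, lay above that, which argues against an exchange in the tables for both pairs. At 15 genes that separated the genotypes, 0 of the 4 lay nearer the other genotype, which argues against an exchange of genotypes. The test used the measured response, so an exchange in the count files stays a hypothesis, and plants that responded unlike their group stay open as untested.

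In the fits of all groups with the tables' labels and of the 8 libraries, more genes were called under drought in ICC283 than in ICC8261. The order turned when each genotype was fitted alone with the tables' labels (4523 and 5242), but not in the 8 libraries (6728 and 2491). The authors' deposited edgeR tables list 4602 and 5215, and their DESeq2 tables have 5198 and 4738 genes under 0.05. Closer replicates with an equal response could not be tested by the size of the change. In the fits of all groups the spread was shared, so the SEs were near equal. Their medians were 0.236 in ICC283 and 0.231 in ICC8261 in the 8 libraries, and 0.238 and 0.235 with the tables' labels. More calls then had to go with larger changes. Among genes called on average, the median log2 change in the direction of that average was larger in ICC283 than in ICC8261. The ratio was 1.68 in the 8 libraries and 1.42 with the tables' labels. The median SD of log2 CPM within groups with the tables' labels was 0.325 and 0.227 in ICC283 and 0.19 and 0.22 in ICC8261 (well-watered, drought), and in the 8 libraries 0.19 and 0.147 against 0.14 and 0.176. Without ICC8261 drought library 3, whose PC1 score of -12.1 lay between the treatments, the ICC8261 count was 3294 beside 7539 in ICC283 in the 8 libraries, and 3588 beside 6766 with the tables' labels. Both gaps exceed 1.5 times, which argues against that library as the cause, but the genotypes then had unequal numbers of libraries. In a comparison chosen after these counts were seen, 1 ICC283 drought library was left out instead: ICC283 then had 3961 and 4996 in the 8 libraries, and 4642, 5188 and 6604 with the tables' labels. These lie on both sides of 1.5 times the ICC8261 counts, so a weaker treatment of library 3 cannot be told apart from a smaller response of the genotype, which may remain. Unequal drying of the pots was not tested.

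Other splits of the samples were fitted the same way. For the average and the difference, the 100 splits counted were the real one and a random draw of the others. With the tables' labels the averaged drought effect had 8177 calls, and 1 of 100 splits, the real one, gave as many (highest other 3289). This excludes chance only if the tables' labels are taken as given. They were adopted here after the results were seen, and preferring them rests partly on the drought response, so chance stays open without them. For the difference between the drought effects 6 of 100 splits, the real one among them, gave as many as the real 479. The highest in the draw was 3065, so chance is not excluded. A split with several times the real count points to a structure of the samples, since such splits mix the drought effect into the difference. With the count-file labels the real count was 0 for the difference (highest other 3289) and the average (8177), so 100 of 100 splits giving as many was fixed beforehand and says nothing.

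The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. The real value and the highest other were 0 and 4339 for drought in ICC283 and 0 and 60 in ICC8261 with the count-file labels, where 10 of 10 splits giving as many as 0 was fixed beforehand. They were 6831 and 0, and 3468 and 0, with the tables' labels, where 1 of 10 did. For the genotypes they were 98 and 0 well-watered and 113 and 90 under drought with the count-file labels, and 2356 and 0, and 1913 and 0, with the tables' labels, again 1 of 10 each.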

How the results depend on the processing

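The tables' labels and the 8 agreed libraries were chosen after the data had been seen; the other settings were planned, and the replicate block within genotype was not run for the 8 libraries. Between them the label versions moved every count: from the count files to the tables to the 8 libraries, 0, 6831 and 7167 for drought in ICC283, 0, 3468 and 2898 in ICC8261, 0, 479 and 2355 for the difference, 0, 8177 and 7567 for the average, 98, 2356 and 4992 for the genotypes well-watered, and 113, 1913 and 3551 under drought. RLE and upper-quartile scaling, the filters, leaving out the most abundant genes and robust estimation kept all counts within 1.5 times.

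With DESeq2 the count-file labels gave 46 in ICC283, 22 on average, 694 well-watered and 460 under drought, and the tables' labels 1269 for the difference. An absolute log2 fold change of at least 1 left, by construction, 3628, 1654, 2930, 1056 and 1036 with the tables' labels (ICC283, ICC8261, average, well-watered, drought), 3892, 1250, 2834, 2239 and 1816 in the 8 libraries, and overlaps of 1079 and 720. Fits of only the libraries compared gave 28 and 3 for the genotypes with the count-file labels, and 4523, 5242 and 1167 (ICC283, ICC8261, well-watered) with the tables' labels.

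The replicate numbers did not pair the libraries: correlations of same-numbered libraries ran from -0.6 to 0.7 with the count-file labels and from -0.09 to 0.26 with the tables'. With the replicate block across all groups the counts were 50 and 45 for the genotypes with the count-file labels, and 1800 for ICC8261 and 3182 well-watered in the 8 libraries; the block within genotype gave 15 list calls in the 4 drought contrasts with the tables' labels, against 8. Camera with an estimated correlation called 1, 0 and 0 lists (count files, tables, 8 libraries; the 1 is the flowering regulators under drought), against 17, 13 and 17, and fry called 3, 33 and 38.

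Leaving out 1 library gave these ranges. Count-file labels: 0 to 417 in ICC283 (highest without well-watered library 3), 0 to 0 in ICC8261, for the difference and on average, 26 to 929 well-watered and 27 to 789 under drought. Tables' labels: 4642 to 7059, 1510 to 4833, 55 to 2298, 6937 to 8533, 697 to 5449 and 628 to 3034. The 8 libraries, where a lone library is assumed to vary like the other groups: 3961 to 7539, 455 to 3294, 540 to 2307, 5453 to 7422, 1434 to 5594 and 862 to 3793.

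Of 245 named values, 216 kept their direction but lost the call with the count-file labels, 14 without the filter, 11 with DESeq2, 11 with the replicate block, 7 and 2 in fits of 1 genotype or treatment, 3 with upper-quartile scaling, and 0 with the tables' labels, a condition of naming. In fits leaving out 1 library 1686 values stayed on the same side of 0.05, 270 lost the call and 2 gained it. With the count-file labels the sign turned for CA-EXPA2 (0.55), ACTIN (0.10), EXPA1 (0.40), XTH1 (0.49) and lrr (0.02) in ICC283, for CAPLEA-1 (-0.29), TOC1A (-0.13), P5CS (-0.43), CAGOLS1 (0.02) and UGT85H3 (0.25) in ICC8261, and for ARF20 (-0.07), CAMAPK5 (0.00), ycf3 (0.08), CAM (0.03) and CA-EXPA2 (0.20) on average. For the difference it turned for CapLEA-2 (0.04) and DHN (0.10) with the tables' labels and without ICC8261 well-watered library 3 for 1 more gene. For CAPLEA-1, difference between the drought effects ranged from -1.96 to 3.13 when 1 library was left out, the latter without that library. CAGOLS1 in ICC8261 ranged likewise from -0.30 to 0.06, the latter without that library. Apart from the fold limit and the smaller fits, the cause was not tested. Depth of 8910704 to 12192098 counts limits genes near the filter.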

Other observations

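The neighbour test was planned before its result was seen; the plastid genes were looked at after the data had been seen.

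Called drought changes of plastid-encoded genes went in both directions. In ICC283 under drought petD rose (0.84 ± 0.15) and petB rose (0.67 ± 0.17), both of the cytochrome b6f complex, while atpF (-1.24 ± 0.15), rpl2 (-0.74 ± 0.15) and ycf3 (-0.67 ± 0.12) fell, in the 8 agreed libraries (log2 ± SE, n = 2 per group). In ICC8261 petD rose (0.93 ± 0.15) and atpF had a value of 0.27 ± 0.15 (adjusted p = 0.25). Camera gave the 10 genes adjusted p = 0.58 in ICC283 and 0.76 in ICC8261, and the estimated correlation between the members was 0.81 in the ICC283 test, 0.36 with the tables' labels. The list took between 5.12% and 8.16% of the counts of a library. Of the 3 tested genes of dividing cells and other organs, edgeR called 1 lower under drought in each genotype with the tables' labels, calls that the 8 libraries did not repeat.

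Genes that differed between the genotypes under well-watered conditions may lie in shared stretches of the genome. In the fit of the 8 agreed libraries 2239 such genes were called with an absolute log2 fold change of at least 1. Of these, 2044 had a place in the reference order, and 168 pairs of neighbours differed in the same direction. In 1000 shuffles the mean was 119 and the highest value 151, and the ratio to the mean was 1.41. Genes called under drought in ICC283 in that fit, with the same fold limit, gave 517 pairs against 422, a ratio of 1.22. Neighbours thus also responded together without a genotype difference. The sets differ in size, 2044 and 3679 genes, so the ratios cannot be compared directly. The test was not run with the tables' labels, which called 1056 genes well-watered at this fold limit. Stretches inherited together are a candidate explanation for the excess between the genotypes, and tandem copies sharing reads stay open as untested.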
